A study of Homo sapiens with 12 samples.

How the data were processed

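RNA of the human promyelocytic leukaemia line HL-60 was sequenced in 12 libraries, 3 in each of 4 groups. Cells had been kept for 36 h with DMSO as vehicle, with decitabine (DAC) at 0.5 µM, with simvastatin (SIMVA) at 10 µM, or with both drugs at those doses (COMBO). Per the labels, total RNA was taken with a column kit, 1 µg of it was selected by poly(A) and depleted of ribosomal RNA, and random primers were used for the cDNA. The strand of the libraries is not stated there. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these libraries.

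The deposited table of counts gives read counts per gene as the authors made them. A second deposited table gives TPM (transcript abundance scaled to a fixed sum per library) per gene, computed by the authors. The submitters' processing notes name FastQC, HISAT2, DESeq2 and the GRCh38 build, with no version and no parameters. The program that counted reads and the annotation release are not given in the sources used here. The table holds 60616 genes, of which 60597 carried a symbol and 58385 had a position in GENCODE v29 on GRCh38. Positions given in the report come from that release, so they rest on matching gene identifiers. Totals ran from 19313917 to 25320708 counts per library. Counting intervals and floors cover counting error only, and bootstrap intervals cover the spread over genes.

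Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups, which left 15000, and libraries were scaled by TMM. All 12 libraries went into one quasi-likelihood fit of group means with 8 residual degrees of freedom. Each of the 6 contrasts was tested with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05, and counts with an absolute log2 fold change of at least 1 were taken as well. The contrasts were DAC vs DMSO, SIMVA vs DMSO, COMBO vs DMSO, COMBO vs DAC, COMBO vs SIMVA, and the interaction, which is the log2 change of COMBO over SIMVA minus that of DAC over DMSO. The common dispersion was 0.00773, a biological coefficient of variation of 8.79%. Levels are given as CPM (counts scaled to a fixed library size, with the TMM factors), mean ± SD of 3 libraries, and log2 fold changes as estimate ± SE. Where a group held no count for a gene, the fold was computed against a floor of 3 counts over the group and is written "at least". Where it held 1 to 3 counts, the ratio is given with its 95% counting interval.

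The groups, contrasts, test, filter, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The 25 lists hold 798 entries, of which 797 matched a gene. They cover sterol synthesis, fatty acid synthesis, sterol efflux, small GTPases and statin-responsive KLF factors, mitosis and the spindle, cohesin and condensin, centrosome and tubulin, G1/S and replication, DNA repair, p53 targets, DNA methylation, decitabine metabolism, germline genes, interferon response, antigen presentation, myeloid maturation, myeloid progenitor and granule genes, erythroid and megakaryocyte genes, lymphoid genes, stress response, apoptosis, NF-kB and inflammation, ribosome biogenesis, histones, and RNA encoded by the mitochondrial genome. Each list with at least 5 tested members was compared with all other tested genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over 144 list and contrast tests. Camera with an estimated correlation and fry were run beside it. Members called were counted with adjustment over all tested genes and over the list alone. The filter keeps genes with counts in at least one group, so list members without counts in every group are not among the measured ones.

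Named genes followed 4 parts of the rule. The largest changes were the 5 highest and 5 lowest log2 fold changes per contrast among called protein-coding genes with a mean of at least 5 CPM in the higher group and, for pairwise contrasts, all 3 libraries of one group above all 3 of the other. Each list named 2 genes in advance. Up to 4 called members with the largest change and at least 1 CPM were taken per list and contrast. The interaction added its 5 highest and 5 lowest called genes. Some genes that the rule names are not reported here. A gene named outside the rule is said to have been chosen after its values were seen.

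Alternatives were DESeq2 size factors in edgeR, library size without scaling factors, no low-count filter, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, a fit of the compared groups alone, the replicate number as a block, limma on log2(TPM + 1) and log2(TPM + 0.1), limma on TPM without the filter, and each library left out in turn. The filter was run again on the libraries left in each of these last fits. The DESeq2 Wald test changed scaling and test together, limma on TPM the measure, scaling and test, and its fit without the filter the filter as well. Chosen after seeing the data were a prior count of 2 in the fit, in place of 0.125, and the counts without 290 genes. Of those, 56 had replicates that differed at least 5-fold in a group, and 240, with 6 in both sets, had more than 70.0% of their 10 nearest protein-coding genes near 0. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. The pipeline was tested on simulated data of 13547 genes, in which it recovered 46 of 67 genes (68.7%) changed 1.5-fold, 57 of 67 (85.1%) changed 2-fold and 63 of 66 (95.5%) changed 4-fold in the simulated DAC vs DMSO. There, 10 of 176 calls (5.68%) were false. The changed genes were all drawn from those above about 1 CPM in DMSO, so the recovered shares do not cover genes under that level.

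Raw reads were not analysed here. All 37 genes of the mitochondrial genome hold no counts in the table, so the mitochondrial list had 0 measured members and RNA quality could not be read from it. Transcripts, splicing and allele use were not analysed here, since the tables give whole genes.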

Results

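Gene expression was measured by RNA sequencing in HL-60 cells, a human promyelocytic leukaemia line, after 36 h with vehicle (DMSO), with 0.5 µM decitabine (DAC), a cytidine analogue that is built into DNA and traps DNA methyltransferases, with 10 µM simvastatin (SIMVA), a statin that blocks the mevalonate pathway, or with both drugs (COMBO). Each group had 3 libraries. The title of the series names mitotic perturbation as a way decitabine acts in myeloid tumours, and the design lets each drug be read alone, on top of the other, and against the sum of both. Library totals were 21296719, 22334514 and 19850169 counts in DMSO, 22483995, 21952540 and 21996298 in DAC, 19313917, 20892077 and 20355802 in SIMVA and 25320708, 23499287 and 24705412 in COMBO. At equal depth, 18336 ± 171 genes had a count in DMSO, 20666 ± 151 in DAC, 19437 ± 455 in SIMVA and 21208 ± 56.6 in COMBO. Each treated group lay wholly above DMSO in this measure (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The 10 most abundant genes took 5.43% ± 0.0637 of counts in DMSO, 4.97% ± 0.0234 in DAC, 6.81% ± 0.0766 in SIMVA and 6.29% ± 0.0588 in COMBO. Libraries separated by each drug on the first 2 principal components.

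**Figure D1:**
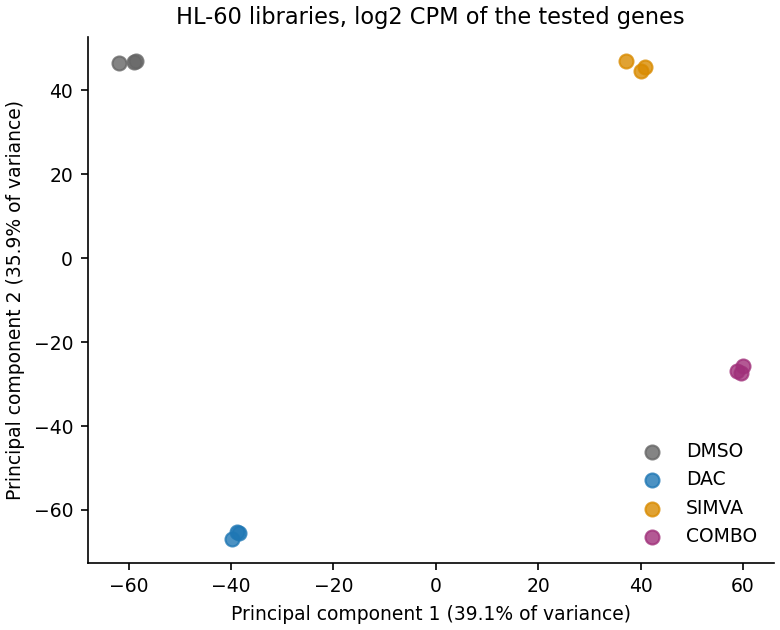
Principal components of log2 CPM of the 12 libraries, one point per library, coloured by group, with the share of variance on each axis in percent. Component 1 (39.1%) parts libraries with simvastatin from those without it, and component 2 (35.9%) parts libraries with decitabine from those without it.

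What decitabine alone changed was read from DAC against DMSO. Genes with no RNA in vehicle cells gave the largest rises. PNMA5 (ENSG00000198883, chromosome X, 152988824 to 152994127), a gene of the paraneoplastic antigen family, had no count in DMSO and stood at 288 ± 17.3 CPM with decitabine (SD, n = 3), at least 5699.9-fold higher. DAZL (ENSG00000092345, chromosome 3, 16586792 to 16670306), which encodes an RNA-binding protein of germ cells, went from no count to 76.8 ± 6.07 CPM, at least 1521-fold. MPO (ENSG00000005381, chromosome 17, 58269856 to 58280935), the myeloperoxidase of granules, rose from 154 ± 2.82 to 1624 ± 39.2 CPM (log2 fold change 3.40 ± 0.05, adjusted p = 2.32e-20). MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434), a driver of ribosome production and growth, stood at 919.5 ± 30.0 CPM in DMSO and 377 ± 10.3 CPM in DAC, and genes of ribosome biogenesis fell together.

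In this comparison, 3222 of 15000 tested genes were higher and 3170 lower at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At 2-fold or more, 1423 were higher and 186 lower. Of those 1423, 998 (70.1%) lay under 1 CPM in DMSO and 254 had no count there. Scaled by library size alone, 3981 genes were higher and 2236 lower, so the share of calls that were higher was 64.0% in place of 50.4%.

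Of 76 germline entries 29 passed the filter. The measured share, the number that rose and the list test are likewise in part set by it in contrasts that involve decitabine. Of these, 29 of 29 measured genes rose and 0 fell, 29 and 0 adjusted over the list alone (median log2 fold change 7.56, camera adjusted p = 2.70e-20, adjusted p = 5.80e-04 with an estimated correlation). With genes without counts set at their bound, that median was 4.95. Besides DAZL, CTCFL, a testis paralogue of the insulator protein CTCF, was at least 97.4-fold higher and MAGEB1 at least 78.4-fold higher. Members of the MAGE-A and CTAG families are near-identical copies, so reads can be shared among them. Other large rises were TEX13C, a testis-expressed gene, at least 504-fold, CD93, a C-type lectin receptor of myeloid and endothelial cells, at least 235-fold, and ZNF595 at least 182-fold.

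Myeloid maturation genes mostly rose: 24 of 39 measured genes rose and 5 fell, 24 and 7 adjusted over the list alone (median log2 fold change 0.90, camera adjusted p = 3.31e-05, adjusted p = 0.00916 with an estimated correlation). CYBB, the catalytic subunit of the phagocyte NADPH oxidase, rose by 3.6 ± 0.22, ITGAX (CD11c) by 3.0 ± 0.32, and ITGAM (ENSG00000169896, chromosome 16, 31259967 to 31332892), which encodes CD11b, by 2.74 ± 0.14 on the log2 scale, from 1.3 ± 0.194 to 8.72 ± 0.763 CPM. In the list of progenitor and granule genes 9 of 20 measured genes rose and 5 fell, 9 and 6 adjusted over the list alone (median log2 fold change 0.06, camera adjusted p = 0.165). Its risers included the eosinophil granule genes PRG2 (3.47 ± 0.43), RNASE3 (2.20 ± 0.24) and RNASE2 (1.70 ± 0.11). Of the erythroid and megakaryocyte genes 4 of 7 measured genes rose and 0 fell, 4 and 0 adjusted over the list alone (median log2 fold change 1.34, camera adjusted p = 0.00410, adjusted p = 0.0502 with an estimated correlation). Among them GATA2, a transcription factor of progenitors and mast cells, rose from 56.3 ± 1.83 to 458 ± 18.1 CPM, and NFE2 rose by 1.34 ± 0.06. Of this list's 29 entries only 7 passed the filter, so its median and test can be in part set by the filter, as for germline genes. Only 5 lymphoid genes were measured, and 1 of them, TRAC, the constant part of the T cell receptor alpha chain, rose by 3.53 ± 0.28 (median log2 fold change 1.11, camera adjusted p = 0.267, 0.0104 without the low-count filter).

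Ribosome biogenesis genes fell nearly as a whole: 0 of 32 measured genes rose and 30 fell, 0 and 30 adjusted over the list alone (median log2 fold change -0.49, camera adjusted p = 3.37e-14, adjusted p = 0.00104 with an estimated correlation). NCL (ENSG00000115053, chromosome 2, 231453531 to 231483641), the nucleolar protein nucleolin, fell from 4351 ± 25.5 to 2878 ± 54.6 CPM, and POLR1B, a subunit of RNA polymerase I, changed by -0.76 ± 0.07 on the log2 scale. Of the stress response genes, 8 of 30 measured genes rose and 15 fell, 8 and 15 adjusted over the list alone (median log2 fold change -0.25, camera adjusted p = 0.214, 0.0448 without the low-count filter), with SESN2 (-1.15 ± 0.11) and the amino acid transporter gene SLC7A5 (-1.07 ± 0.05) falling and the chaperone cofactor gene DNAJB9 (1.00 ± 0.12) rising. Of the genes that carry or convert decitabine, 3 of 13 measured genes rose and 8 fell, 3 and 8 adjusted over the list alone (median log2 fold change -0.29, camera adjusted p = 0.0346, adjusted p = 0.0927 with an estimated correlation). CDA, the cytidine deaminase that inactivates the drug, rose by 2.88 ± 0.36 from 0.567 ± 0.467 CPM, while the nucleoside carrier gene SLC29A1 (-0.48 ± 0.05) and SAMHD1, a triphosphohydrolase of deoxynucleotides (-0.74 ± 0.06), fell.

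Cell division genes moved by small amounts. Of the G1/S and replication genes, 17 of 46 measured genes rose and 4 fell, 17 and 4 adjusted over the list alone (median log2 fold change 0.11, camera adjusted p = 0.00756, adjusted p = 0.0434 with an estimated correlation), and with library size alone 29 rose and 1 fell. E2F8, a repressor of the E2F family, rose by 1.34 ± 0.08, and RRM2, the small subunit of ribonucleotide reductase, by 0.55 ± 0.04. Of the mitosis and spindle genes, 25 of 69 measured genes rose and 4 fell, 25 and 4 adjusted over the list alone (median log2 fold change 0.14, camera adjusted p = 0.0214, adjusted p = 0.558 with an estimated correlation), and with library size alone 42 rose and 2 fell. HJURP, the chaperone of the centromere histone, rose by 0.54 ± 0.06, CEP55 by 0.54 ± 0.07 and MKI67 by 0.44 ± 0.06. PLK1, a kinase that drives mitosis, stood at -0.16 ± 0.05 (adjusted p = 0.0127, 0.221 when scaled by library size alone, 0.0620 without DAC replicate 1 and at most 0.248 over all alternatives). CCNB1, a cyclin of mitosis, was not called (0.05 ± 0.06, adjusted p = 0.534). The list's own call was lost without DMSO replicate 2 (adjusted p = 0.0849), DMSO replicate 3 (0.0897) or DAC replicate 1 (0.0804). In cohesin and condensin, 7 of 24 measured genes rose and 1 fell, 7 and 1 adjusted over the list alone (median log2 fold change 0.10, camera adjusted p = 0.107), and with library size alone 13 rose and 0 fell and the list was called (adjusted p = 0.0201), as it was without DAC replicate 2 (0.0467). SGO1, a guardian of centromere cohesion, rose by 0.63 ± 0.12. In the centrosome and tubulin list, 12 of 28 measured genes rose and 1 fell, 13 and 1 adjusted over the list alone (median log2 fold change 0.17, camera adjusted p = 0.0556), with STIL at 0.38 ± 0.07 and MAP4 at -0.42 ± 0.05. That list was called with library size alone (adjusted p = 0.0172), where 18 rose and 1 fell, with the filter at 1 CPM (0.0244), and without DAC replicate 2 (0.0344) or DMSO replicate 1 (0.0416). TUBB, the main beta tubulin gene, was listed near 0 in all groups and gives no level.

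Of the DNA repair genes, 13 of 42 measured genes rose and 5 fell, 13 and 5 adjusted over the list alone (median log2 fold change 0.10, camera adjusted p = 0.238), and BRCA2 rose by 0.60 ± 0.08. Of the p53 target genes, 9 of 22 measured genes rose and 7 fell, 9 and 7 adjusted over the list alone (median log2 fold change 0.08, camera adjusted p = 0.745). CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), which encodes the cyclin-dependent kinase inhibitor p21, rose from 1.27 ± 0.460 to 9.29 ± 1.88 CPM, and MDM2 was not called (0.01 ± 0.07, adjusted p = 0.918). In the DNA methylation machinery, 4 of 15 measured genes rose and 3 fell, 4 and 3 adjusted over the list alone (median log2 fold change 0.09, camera adjusted p = 0.540). DNMT1, the maintenance methyltransferase that decitabine traps, had a log2 fold change of 0.05 ± 0.04 (adjusted p = 0.398), but was called higher with library size alone (0.13, adjusted p = 0.0135) and on TPM (0.13, adjusted p = 0.0157 to 0.0214), and HELLS rose by 0.38 ± 0.07.

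Interferon response genes went up on balance: 15 of 41 measured genes rose and 2 fell, 15 and 2 adjusted over the list alone (median log2 fold change 0.29, camera adjusted p = 0.0306, adjusted p = 0.166 with an estimated correlation). LGALS3BP rose by 4.21 ± 0.21, OAS3, a sensor of double-stranded RNA, by 3.58 ± 0.58, and MX2 by 1.58 ± 0.16. The list's call was lost without DMSO replicate 3 (adjusted p = 0.0736) or DAC replicate 2 (0.0773). Of the NF-kB and inflammation genes, 11 of 16 measured genes rose and 2 fell, 12 and 2 adjusted over the list alone (median log2 fold change 0.62, camera adjusted p = 0.00286, adjusted p = 0.0312 with an estimated correlation). PTGS2, the inducible cyclooxygenase, rose by 4.37 ± 0.30 and CCL2 by 2.56 ± 0.49. Antigen presentation had 12 measured genes of 27 entries, since most genes of the MHC block were listed near 0, and 5 of 12 measured genes rose and 3 fell, 5 and 3 adjusted over the list alone (median log2 fold change 0.17, camera adjusted p = 0.478). Of the apoptosis genes, 10 of 31 measured genes rose and 7 fell, 10 and 7 adjusted over the list alone (median log2 fold change 0.06, camera adjusted p = 0.359), with BIK at 2.51 ± 0.43 and CASP6 at 1.02 ± 0.15.

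Genes of lipid metabolism moved little with decitabine. In sterol synthesis, 11 of 24 measured genes rose and 4 fell, 12 and 4 adjusted over the list alone (median log2 fold change 0.13, camera adjusted p = 0.145). In fatty acid synthesis, 7 of 15 measured genes rose and 4 fell, 7 and 4 adjusted over the list alone (median log2 fold change 0.08, camera adjusted p = 0.567), with the desaturase gene FADS2 at 0.65 ± 0.08 and SCD at -0.41 ± 0.04. In sterol efflux, 4 of 9 measured genes rose and 0 fell, 4 and 0 adjusted over the list alone (median log2 fold change 0.33, camera adjusted p = 0.142), with NPC1 at 0.60 ± 0.06. Among small GTPase and KLF genes, 10 of 27 measured genes rose and 4 fell, 10 and 4 adjusted over the list alone (median log2 fold change 0.08, camera adjusted p = 0.182), with RHOH at 3.75 ± 0.43 and RHOC at 2.06 ± 0.20. Of the histone genes, 6 of 18 measured genes rose and 1 fell, 6 and 1 adjusted over the list alone (median log2 fold change 0.44, camera adjusted p = 0.0655, 0.0244 with the filter at 1 CPM), with H2BC21 at 1.6 ± 0.18. Among the largest falls were CACNA2D3, an auxiliary calcium channel subunit (-2.30 ± 0.23), and LMF1, a lipase maturation factor (-1.91 ± 0.24). The rule also named HMOX2 (5.05 ± 6.15 CPM in DMSO), DNAJA3 (52.8 ± 16.0 CPM) and SINHCAF (9.77 ± 11.1 CPM), whose replicates disagreed by these SDs, so no fall is read from them.

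**Figure D2:**
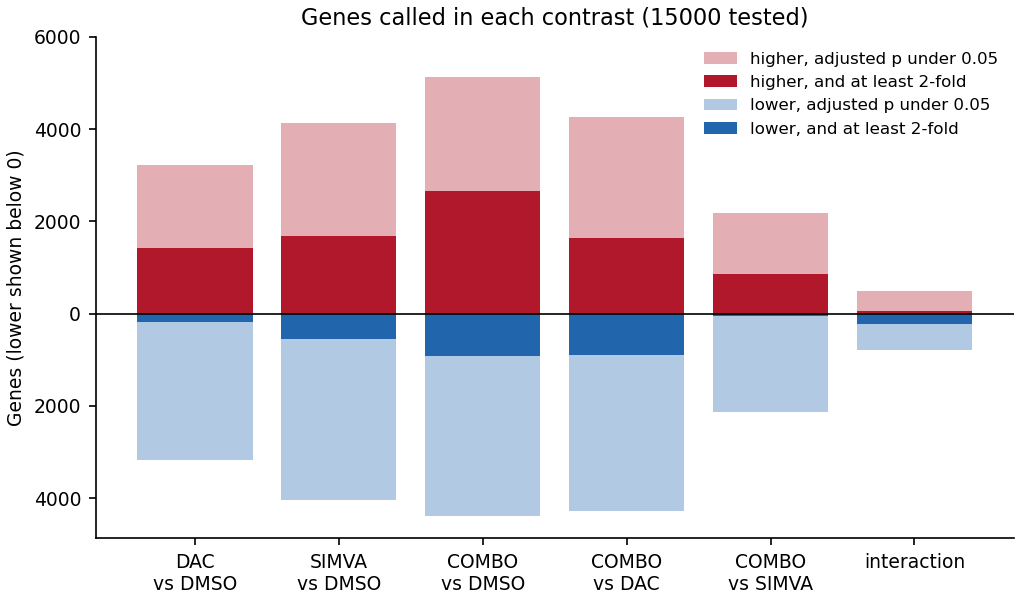
Genes called at an adjusted p under 0.05 in each of the 6 contrasts, higher to one side and lower to the other, with the part that changed at least 2-fold marked. Higher and lower calls are similar in number in the pairwise contrasts, for example 3222 and 3170 in DAC vs DMSO, while 2-fold changes are mostly rises; scaled by library size alone, higher calls outnumber lower ones in all pairwise contrasts (3981 and 2236 in DAC vs DMSO).

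SIMVA against DMSO asked what the statin alone changed. Genes of sterol synthesis rose together, among them HMGCS1 (ENSG00000112972, chromosome 5, 43289395 to 43313512), an early enzyme of the mevalonate pathway, from 95.2 ± 8.82 to 562 ± 11.7 CPM (SD, n = 3; log2 fold change 2.56 ± 0.06, adjusted p = 2.26e-18). ABCA1 (ENSG00000165029, chromosome 9, 104781002 to 104928237), the exporter of cholesterol, fell from 77.9 ± 2.29 to 3.53 ± 0.567 CPM. KLF2 (ENSG00000127528, chromosome 19, 16324817 to 16327874), a transcription factor, rose from 1.02 ± 0.554 to 202 ± 42.8 CPM, and ITGAM from 1.3 ± 0.194 to 57.7 ± 4.36 CPM, while MPO fell to 30.6 ± 2.14 CPM. Most genes of mitosis, of G1/S and of ribosome biogenesis that were measured fell.

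There were 4134 genes higher and 4048 lower, and at 2-fold or more 1689 higher and 554 lower. Of the 1689, 818 (48.4%) lay under 1 CPM in DMSO and 56 had no count there. With library size alone, 5008 were higher and 3221 lower (60.9% higher in place of 50.5%), and the median log2 fold change of all genes went from 0.03 to 0.14. It went from 0.09 to 0.28 in COMBO vs DMSO and from 0.03 to 0.13 in COMBO vs DAC.

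Of the sterol synthesis genes, 23 of 24 measured genes rose and 0 fell, 23 and 0 adjusted over the list alone (median log2 fold change 1.47, camera adjusted p = 6.83e-14, adjusted p = 6.38e-04 with an estimated correlation). TM7SF2, a sterol reductase, rose by 3.20 ± 0.13. Fatty acid genes split, and 7 of 15 measured genes rose and 5 fell, 7 and 5 adjusted over the list alone (median log2 fold change 0.04, camera adjusted p = 0.315): ACSS2, which makes acetyl-CoA from acetate, rose by 3.47 ± 0.08 and FADS1 by 1.46 ± 0.05, while FASN was not called (0.04 ± 0.05, adjusted p = 0.486) except with library size alone (0.15, adjusted p = 0.0153). Of the sterol efflux genes, 5 of 9 measured genes rose and 3 fell, 5 and 3 adjusted over the list alone (median log2 fold change 0.45, camera adjusted p = 0.644), and beside ABCA1 (-4.46 ± 0.10) MYLIP, a ubiquitin ligase gene, fell (-1.56 ± 0.09), while NPC2 rose (1.85 ± 0.10). Of the small GTPase and KLF genes, 12 of 27 measured genes rose and 4 fell, 12 and 4 adjusted over the list alone (median log2 fold change 0.19, camera adjusted p = 0.0468, adjusted p = 0.0927 with an estimated correlation). KLF2 rose by 7.63 ± 0.23, RHOC by 3.92 ± 0.18 and KLF6 by 2.98 ± 0.08. That list's call was lost without DMSO replicate 2 (adjusted p = 0.0620), DMSO replicate 3 (0.0644), SIMVA replicate 1 (0.0518) or SIMVA replicate 3 (0.0534).

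Of the mitosis and spindle genes, 6 of 69 measured genes rose and 52 fell, 6 and 53 adjusted over the list alone (median log2 fold change -0.36, camera adjusted p = 3.63e-08, adjusted p = 0.196 with an estimated correlation). PLK1 (ENSG00000166851, chromosome 16, 23677656 to 23690367) fell from 239 ± 10.4 to 104 ± 3.15 CPM. CDC20, the activator of the anaphase-promoting complex, had a log2 fold change of -1.15 ± 0.05 and AURKA, a mitotic kinase, of -0.88 ± 0.06. Of the cohesin and condensin genes, 2 of 24 measured genes rose and 15 fell, 2 and 16 adjusted over the list alone (median log2 fold change -0.25, camera adjusted p = 0.0120, adjusted p = 0.472 with an estimated correlation). Members included SMC4, a condensin subunit, at -0.66 ± 0.07 and SMC3 of cohesin at -0.44 ± 0.06. Of the G1/S and replication genes, 7 of 46 measured genes rose and 30 fell, 7 and 31 adjusted over the list alone (median log2 fold change -0.33, camera adjusted p = 2.15e-04, adjusted p = 0.0133 with an estimated correlation), and with library size alone 11 rose and 29 fell. POLA1, of the polymerase that primes replication, fell (-0.75 ± 0.07), and E2F2 rose (0.75 ± 0.07). In the centrosome and tubulin list, whose median (-0.07) and mean (0.16) differ in sign, 7 of 28 measured genes rose and 10 fell, 7 and 11 adjusted over the list alone (camera adjusted p = 0.540), and with library size alone 9 rose and 8 fell. TUBA1A, an alpha tubulin, rose from 51.4 ± 5.24 to 719 ± 55.6 CPM. Tubulin genes are similar in sequence, so reads can be shared among them.

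Myeloid maturation genes rose: 29 of 39 measured genes rose and 3 fell, 29 and 3 adjusted over the list alone (median log2 fold change 0.86, camera adjusted p = 2.76e-07, adjusted p = 0.00301 with an estimated correlation). TLR8 rose by 6.62 ± 0.39 and ITGAM by 5.47 ± 0.12, while CD14 was not called (0.79 ± 0.56, adjusted p = 0.246). In the progenitor and granule list 4 of 20 measured genes rose and 9 fell, 5 and 9 adjusted over the list alone (median log2 fold change -0.31, camera adjusted p = 0.118, 0.0271 without the low-count filter), with CD38 at -1.43 ± 0.12. GATA2 fell (-1.64 ± 0.07) and NFE2 rose (1.91 ± 0.06). Of the interferon genes, 27 of 41 measured genes rose and 3 fell, 27 and 3 adjusted over the list alone (median log2 fold change 0.69, camera adjusted p = 1.05e-04, adjusted p = 0.0327 with an estimated correlation). Members included TRIM22 at 2.96 ± 0.14 and IFI16, a DNA sensor, at 2.11 ± 0.14, while ISG15 was not called (0.03 ± 0.15, adjusted p = 0.892). Of the NF-kB genes, 10 of 16 measured genes rose and 4 fell, 10 and 4 adjusted over the list alone (median log2 fold change 0.76, camera adjusted p = 0.0282, adjusted p = 0.0831 with an estimated correlation). Members included BCL3 at 2.21 ± 0.21. CDKN1A rose from 1.27 ± 0.460 to 14.1 ± 0.918 CPM, and of the p53 target genes 12 of 22 measured genes rose and 5 fell, 13 and 5 adjusted over the list alone (median log2 fold change 0.45, camera adjusted p = 0.0667, 0.0357 without the low-count filter and 0.0460 without DMSO replicate 3).

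Ribosome biogenesis genes fell: 0 of 32 measured genes rose and 30 fell, 0 and 30 adjusted over the list alone (median log2 fold change -0.77, camera adjusted p = 1.72e-14, adjusted p = 0.00104 with an estimated correlation). NCL fell by 1.07 on the log2 scale and ODC1, the first enzyme of polyamine synthesis, had a log2 fold change of -2.12 ± 0.05. Of the stress response genes, 4 of 30 measured genes rose and 19 fell, 4 and 19 adjusted over the list alone (median log2 fold change -0.64, camera adjusted p = 2.57e-05, adjusted p = 0.0230 with an estimated correlation). Members included the serine synthesis gene PSAT1 at -1.97 ± 0.06 and the cystine carrier gene SLC7A11 at -2.34 ± 0.12. Of the histone genes, 8 of 18 measured genes rose and 1 fell, 8 and 1 adjusted over the list alone (median log2 fold change 0.76, camera adjusted p = 0.0349, adjusted p = 0.113 with an estimated correlation). That call was lost without any 1 of the 3 DMSO or 3 SIMVA libraries, and in 8 settings in all, with adjusted p from 0.0624 to 0.117. SAMHD1 rose (1.28 ± 0.06) and SLC29A1 fell (-0.73 ± 0.05). Of the germline genes, 4 of 29 measured genes rose and 1 fell, 2 and 1 adjusted over the list alone (median log2 fold change 0.00, camera adjusted p = 0.819), with PIWIL4 at 1.09 ± 0.08, and DAZL had no count in either group. Among the largest changes were LTK, a receptor tyrosine kinase, 503-fold (95% counting interval 89.8 to 19890.0) higher, CD180, a toll-like receptor family member, 437-fold (95% counting interval 121 to 3618) higher, ARHGEF10L (6.31 ± 0.25), RHEX (-3.56 ± 0.23), ADGRG5 (-3.31 ± 0.16) and ANKRD22 (-2.90 ± 0.30). DHX16 was also named by the rule, with replicates that disagreed (8.25 ± 6.70 CPM in DMSO).

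**Figure D3:**
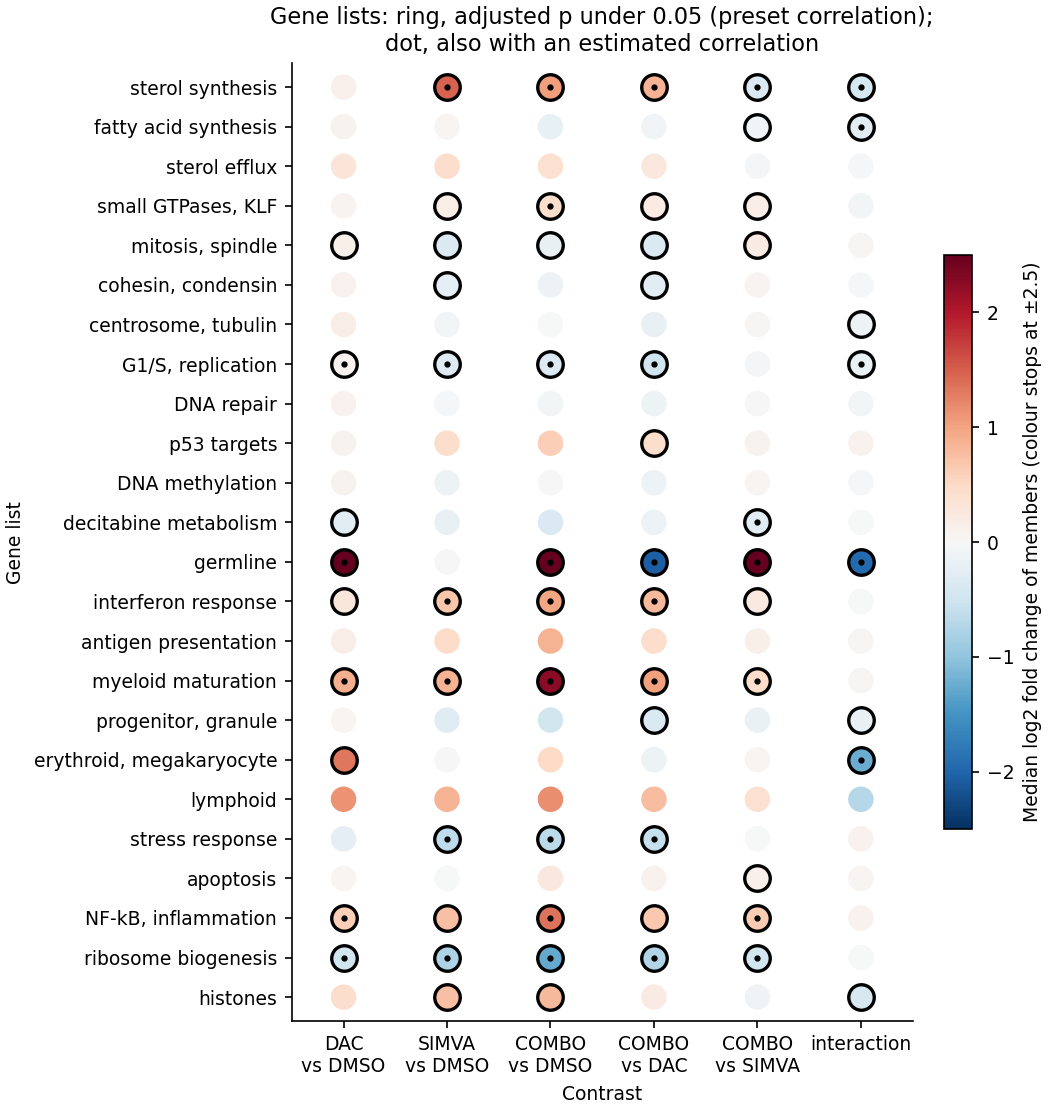
Median log2 fold change of each measured gene list in the 6 contrasts (colour, stopping at 2.5 either way), with a ring for a camera call and a dot where it also held with an estimated correlation. Germline genes are highest in DAC vs DMSO (7.56), sterol synthesis genes in SIMVA vs DMSO (1.47), and ribosome biogenesis genes are lowest in COMBO vs DMSO (-1.29); with library size alone the mitosis list in COMBO vs DMSO loses its direction (22 rose and 22 fell).

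COMBO against DMSO gave the change with both drugs. Maturation genes rose, with ITGAM at 119 ± 3.6 CPM against 1.3 ± 0.194 in DMSO (log2 fold change 6.51 ± 0.12, adjusted p = 4.28e-20, n = 3 libraries per group). Ribosome biogenesis genes fell further, NCL to 1351 ± 20.9 CPM. HMGCS1 stood at 395 ± 5.71 CPM, KLF2 at 189 ± 22.3 CPM and CDKN1A at 27.6 ± 0.673 CPM. DAZL was at least 164-fold higher than in DMSO. RHOB, a small GTPase, had no count in DMSO or SIMVA and 14.7 ± 1.03 CPM here, at least 292-fold higher than in DMSO.

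There were 5137 genes higher and 4390 lower, and at 2-fold or more 2661 and 911. Of the 2661, 1500 (56.4%) lay under 1 CPM in DMSO and 259 had no count there. Library size alone gave 6550 higher and 3202 lower (67.2% higher in place of 53.9%).

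Of the myeloid maturation genes, 31 of 39 measured genes rose and 3 fell, 31 and 3 adjusted over the list alone (median log2 fold change 2.25, camera adjusted p = 5.89e-08, adjusted p = 0.00254 with an estimated correlation). Members included ITGAX at 5.56 ± 0.28, FPR1, a formyl peptide receptor, at 5.36 ± 0.53 and CD14 at 4.04 ± 0.45. Of the ribosome biogenesis genes, 0 of 32 measured genes rose and 30 fell, 0 and 30 adjusted over the list alone (median log2 fold change -1.29, camera adjusted p = 6.33e-17, adjusted p = 6.48e-04 with an estimated correlation). Members included DDX21 at -1.86 ± 0.05. MYC fell by 1.40 and SLC7A5 by 2.54 on the log2 scale. Of the interferon genes, 30 of 41 measured genes rose and 2 fell, 30 and 2 adjusted over the list alone (median log2 fold change 0.98, camera adjusted p = 2.92e-05, adjusted p = 0.0248 with an estimated correlation). Members included OAS3 at 5.60 ± 0.54 and OAS1 at 4.38 ± 0.48. Of the NF-kB genes, 12 of 16 measured genes rose and 1 fell, 12 and 1 adjusted over the list alone (median log2 fold change 1.36, camera adjusted p = 9.55e-04, adjusted p = 0.0223 with an estimated correlation). Members included BCL3 at 3.36 ± 0.20 and the adhesion molecule gene ICAM1 at 2.43 ± 0.14. Of the sterol synthesis genes, 23 of 24 measured genes rose and 1 fell, 23 and 1 adjusted over the list alone (median log2 fold change 1.05, camera adjusted p = 3.46e-08, adjusted p = 0.00219 with an estimated correlation). Of the small GTPase and KLF genes, 18 of 27 measured genes rose and 3 fell, 19 and 3 adjusted over the list alone (median log2 fold change 0.44, camera adjusted p = 0.00410, adjusted p = 0.0311 with an estimated correlation). Of the germline genes, 22 of 29 measured genes rose and 0 fell, 24 and 0 adjusted over the list alone (median log2 fold change 4.08, camera adjusted p = 6.24e-07, adjusted p = 0.00254 with an estimated correlation). With genes without counts at their bound, that median was 2.46. MAEL, which acts in silencing of transposons in germ cells, was 305-fold (95% counting interval 84.1 to 2521) higher.

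Cell division genes were lower than in DMSO in part. Of the G1/S genes, 8 of 46 measured genes rose and 31 fell, 8 and 31 adjusted over the list alone (median log2 fold change -0.38, camera adjusted p = 1.19e-04, adjusted p = 0.0110 with an estimated correlation). Members included UNG, a uracil glycosylase, at -1.13 ± 0.05 and POLA1 at -0.92 ± 0.07. Of the mitosis genes, 12 of 69 measured genes rose and 37 fell, 12 and 37 adjusted over the list alone (median log2 fold change -0.19, camera adjusted p = 0.00567, adjusted p = 0.502 with an estimated correlation), but with library size alone 22 rose and 22 fell and the call was lost (adjusted p = 0.0647). PLK1 stood at -1.27 ± 0.05 and CDC20 at -1.14 ± 0.05. PARP1, which senses DNA breaks, fell (-0.96 ± 0.04), as did DNMT1 (-0.41 ± 0.04). Of the stress response genes, 7 of 30 measured genes rose and 20 fell, 8 and 21 adjusted over the list alone (median log2 fold change -0.67, camera adjusted p = 4.25e-04, adjusted p = 0.0434 with an estimated correlation). Of the histone genes, 10 of 18 measured genes rose and 3 fell, 10 and 3 adjusted over the list alone (median log2 fold change 0.81, camera adjusted p = 0.0450, adjusted p = 0.129 with an estimated correlation). That call was lost without any 1 of the 3 DMSO or 3 COMBO libraries, with library size alone or without the low-count filter, with adjusted p from 0.0731 to 0.228. For p53 targets, 13 of 22 measured genes rose and 4 fell, 13 and 5 adjusted over the list alone (median log2 fold change 0.61, camera adjusted p = 0.101, 0.0453 without the low-count filter), with BTG2, an antiproliferative gene, at 4.0 ± 0.16. CDA rose by 3.72 ± 0.35. Other large changes were PNMA5, at least 1345-fold higher, JUP, the junction protein plakoglobin, at least 181-fold higher, LTK, 1692-fold (95% counting interval 303 to 66879) higher, ABCA1 (-3.41 ± 0.09) and ADGRA3 (-2.54 ± 0.14). CISD3 and DNAJA3 were also named by the rule and had replicates that disagreed (7.29 ± 11.1 and 52.8 ± 16.0 CPM in DMSO).

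**Figure D4:**
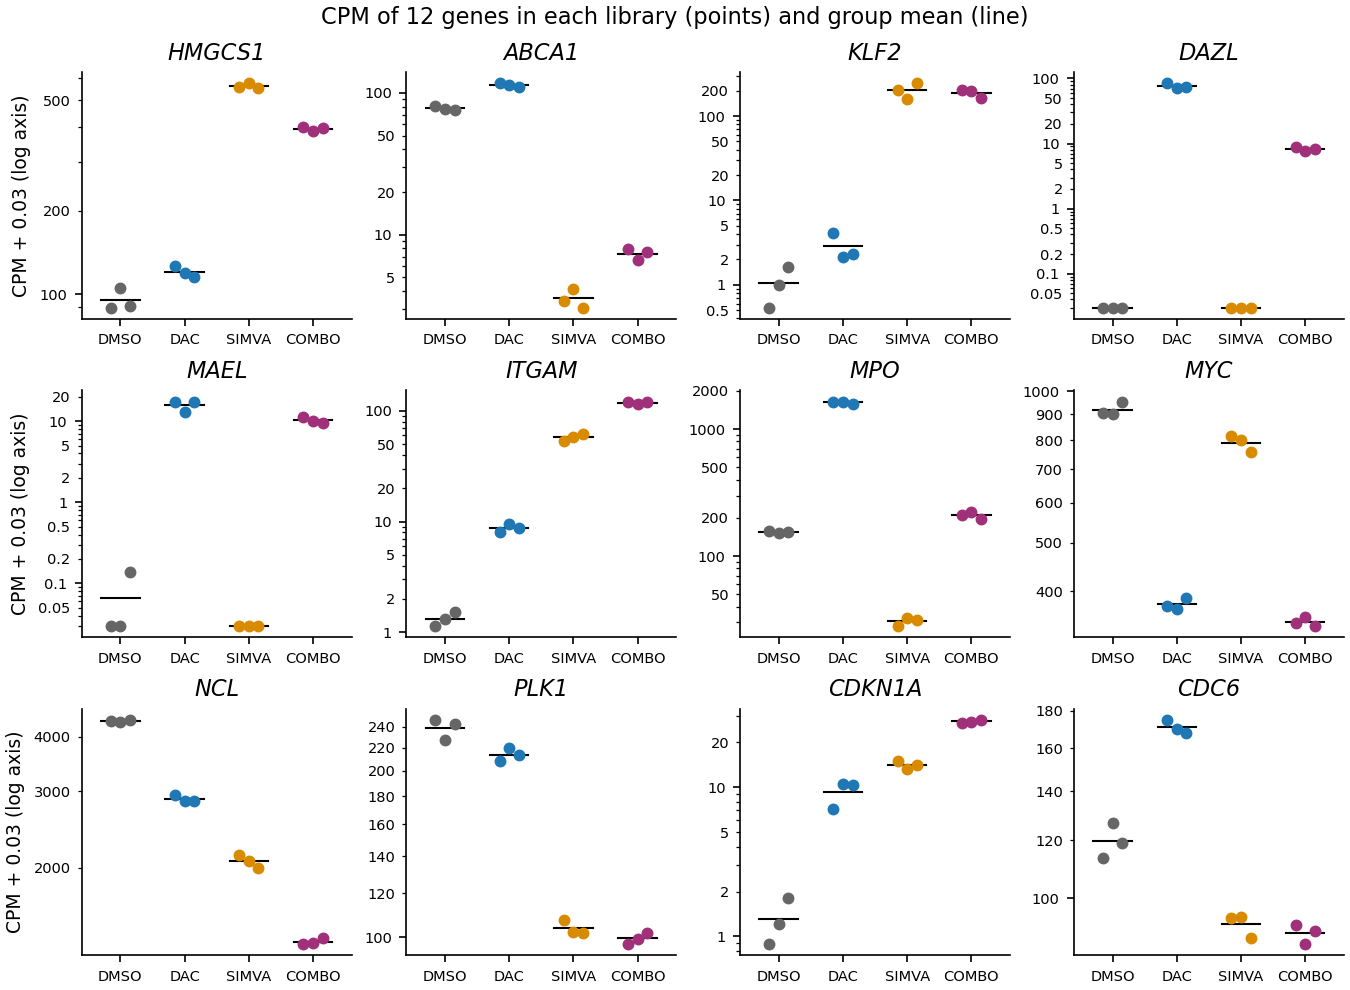
CPM of 12 genes in the 4 groups on log axes (CPM + 0.03), each point a library and each line the mean of 3. HMGCS1 and KLF2 are high with simvastatin and ABCA1 is low, DAZL and MAEL have counts with decitabine, MPO is highest in DAC (1624 CPM), and NCL falls from DMSO to COMBO.

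COMBO against DAC showed what simvastatin did to cells that also had decitabine. Sterol synthesis genes rose again, HMGCS1 from 120.5 ± 5.43 to 395 ± 5.71 CPM. Several genes that decitabine alone had raised were lower with both drugs: DAZL fell from 76.8 ± 6.07 to 8.24 ± 0.646 CPM, MPO from 1624 ± 39.2 to 209.9 ± 11.7 CPM and GATA2 from 458 ± 18.1 to 36.7 ± 2.11 CPM (SD, n = 3). ITGAM rose further, from 8.72 ± 0.763 to 119 ± 3.6 CPM. In all, 4256 genes were higher and 4283 lower, and 1631 and 894 at 2-fold or more. With library size alone, 5090 were higher and 3475 lower.

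Of the germline genes, 1 of 29 measured genes rose and 24 fell, 1 and 24 adjusted over the list alone (median log2 fold change -2.06, camera adjusted p = 7.48e-07, adjusted p = 0.00256 with an estimated correlation). Members included CTCFL at -4.84 ± 0.55 and MAGEA12, which was 61.2-fold (95% counting interval 16.5 to 512) lower. Germline genes could pass the filter through counts in DAC alone, which favours a fall in this contrast. Of the G1/S genes, 4 of 46 measured genes rose and 34 fell, 4 and 34 adjusted over the list alone (median log2 fold change -0.50, camera adjusted p = 5.58e-08, adjusted p = 0.00229 with an estimated correlation). Members included CDC45 at -1.01 ± 0.06, CDC6, a licensing factor of replication origins, at -0.93 ± 0.06 and RRM2 at -0.84 ± 0.04. Of the mitosis genes, 6 of 69 measured genes rose and 50 fell, 6 and 50 adjusted over the list alone (median log2 fold change -0.36, camera adjusted p = 1.01e-06, adjusted p = 0.253 with an estimated correlation). Of the cohesin and condensin genes, 2 of 24 measured genes rose and 16 fell, 2 and 18 adjusted over the list alone (median log2 fold change -0.28, camera adjusted p = 0.00384, adjusted p = 0.439 with an estimated correlation). Of the ribosome biogenesis genes, 0 of 32 measured genes rose and 30 fell, 1 and 30 adjusted over the list alone (median log2 fold change -0.76, camera adjusted p = 1.46e-13, adjusted p = 0.00114 with an estimated correlation). Of the progenitor and granule genes, 3 of 20 measured genes rose and 11 fell, 3 and 11 adjusted over the list alone (median log2 fold change -0.36, camera adjusted p = 0.00616, adjusted p = 0.0919 with an estimated correlation). Of the stress response genes, 3 of 30 measured genes rose and 19 fell, 4 and 19 adjusted over the list alone (median log2 fold change -0.59, camera adjusted p = 1.68e-04, adjusted p = 0.0343 with an estimated correlation). Members included ATF5 at -1.69 ± 0.10.

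Groups that went up on top of decitabine were sterol synthesis, where 21 of 24 measured genes rose and 0 fell, 21 and 0 adjusted over the list alone (median log2 fold change 0.87, camera adjusted p = 4.01e-10, adjusted p = 0.00114 with an estimated correlation), and myeloid maturation, where 31 of 39 measured genes rose and 2 fell, 31 and 3 adjusted over the list alone (median log2 fold change 1.02, camera adjusted p = 2.56e-08, adjusted p = 0.00229 with an estimated correlation). CD36, a scavenger receptor, rose by 5.72 ± 0.47 and TLR8 by 3.93 ± 0.27, while EGR1, an immediate-early transcription factor, fell (-4.18 ± 0.22). Among interferon genes, 28 of 41 measured genes rose and 3 fell, 28 and 4 adjusted over the list alone (median log2 fold change 0.82, camera adjusted p = 1.26e-04, adjusted p = 0.0339 with an estimated correlation). Among small GTPase and KLF genes, 15 of 27 measured genes rose and 6 fell, 15 and 7 adjusted over the list alone (median log2 fold change 0.23, camera adjusted p = 0.0171, adjusted p = 0.0544 with an estimated correlation). Members included KLF2 at 6.07 ± 0.20. For p53 targets, 12 of 22 measured genes rose and 3 fell, 13 and 3 adjusted over the list alone (median log2 fold change 0.45, camera adjusted p = 0.0255, adjusted p = 0.0728 with an estimated correlation). Members included BTG2 at 2.60 ± 0.14 and BBC3, a BH3-only death gene, at 2.24 ± 0.18. Among NF-kB genes, 9 of 16 measured genes rose and 3 fell, 9 and 3 adjusted over the list alone (median log2 fold change 0.67, camera adjusted p = 0.0405, adjusted p = 0.0976 with an estimated correlation), where ICAM1 rose (1.90 ± 0.13) and PTGS2 fell (-2.89 ± 0.26). The NF-kB call was lost with library size alone (adjusted p = 0.0652) and without the low-count filter (0.0506). SAMHD1 rose by 1.83 ± 0.06. Among the largest rises were MUC1, a membrane mucin (7.89 ± 0.29), RHOB (6.86 ± 0.41) and CD180 (6.84 ± 0.32). KCNJ2, a potassium channel, was 174-fold (95% counting interval 47.9 to 1442) higher and AIRE, a regulator of self-antigen expression, 172-fold (95% counting interval 47.2 to 1421) higher. Among the largest falls were TCN1, a cobalamin carrier of granules (-5.91 ± 0.39), SALL2 (-4.87 ± 0.41), RHEX (-4.79 ± 0.11) and EPX, the eosinophil peroxidase (-4.31 ± 0.31).

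COMBO against SIMVA showed what decitabine did to cells that also had simvastatin. Germline genes rose here too: MAEL (ENSG00000143194, chromosome 1, 166975582 to 167022214) had no count in SIMVA and 10.3 ± 0.877 CPM in COMBO, at least 209-fold higher, and DAZL was at least 168-fold higher. MPO rose from 30.6 ± 2.14 to 209.9 ± 11.7 CPM, and MYC fell from 791 ± 30.3 to 348 ± 7.31 CPM (SD, n = 3). Sterol synthesis genes were lower than with simvastatin alone, among them DHCR7, the last reductase of the pathway (-0.72 ± 0.05). There were 2188 genes higher and 2141 lower, and 852 and 49 at 2-fold or more, of which 609 of the 852 (71.5%) lay under 1 CPM in SIMVA and 201 had no count there. Library size alone gave 3093 higher and 1400 lower (68.8% higher in place of 50.5%).

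Of the germline genes, 18 of 29 measured genes rose and 0 fell, 18 and 0 adjusted over the list alone (median log2 fold change 4.08, camera adjusted p = 6.54e-14, adjusted p = 6.24e-04 with an estimated correlation). With genes without counts at their bound, the median was 2.52. Of the ribosome biogenesis genes, 0 of 32 measured genes rose and 28 fell, 0 and 28 adjusted over the list alone (median log2 fold change -0.48, camera adjusted p = 8.37e-19, adjusted p = 6.24e-04 with an estimated correlation). Members included RRP9 at -0.98 ± 0.07. Of the sterol synthesis genes, 0 of 24 measured genes rose and 18 fell, 0 and 19 adjusted over the list alone (median log2 fold change -0.39, camera adjusted p = 5.93e-10, adjusted p = 0.00114 with an estimated correlation). Members included MVD at -0.77 ± 0.10 and ACAT2 at -0.70 ± 0.04. Of the fatty acid genes, 2 of 15 measured genes rose and 5 fell, 2 and 6 adjusted over the list alone (median log2 fold change -0.09, camera adjusted p = 0.0296, adjusted p = 0.129 with an estimated correlation). Members included FASN, the fatty acid synthase, at -0.83 ± 0.05 and SCD at -0.70 ± 0.04. The fatty acid call was lost with library size alone (adjusted p = 0.0573) and without SIMVA replicate 3 (0.0548). Of the genes of decitabine metabolism, 2 of 13 measured genes rose and 8 fell, 3 and 8 adjusted over the list alone (median log2 fold change -0.29, camera adjusted p = 0.00640, adjusted p = 0.0434 with an estimated correlation). Members included CDA at 3.30 ± 0.34 and SLC29A2 at -0.72 ± 0.09.

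Mitosis genes were higher than with simvastatin alone by small amounts: 35 of 69 measured genes rose and 1 fell, 35 and 2 adjusted over the list alone (median log2 fold change 0.20, camera adjusted p = 1.72e-05, adjusted p = 0.318 with an estimated correlation). Members included CENPE, a kinesin of the kinetochore, at 0.46 ± 0.09, HMMR at 0.46 ± 0.08 and PLK1, which was not called (-0.06 ± 0.05, adjusted p = 0.411). Of the myeloid maturation genes, 21 of 39 measured genes rose and 3 fell, 22 and 3 adjusted over the list alone (median log2 fold change 0.47, camera adjusted p = 2.57e-05, adjusted p = 0.00874 with an estimated correlation). Members included LGALS3 (galectin-3) at 4.05 ± 0.24, CD14 at 3.25 ± 0.41 and FPR2 at 2.75 ± 0.17. Of the NF-kB genes, 12 of 16 measured genes rose and 1 fell, 12 and 1 adjusted over the list alone (median log2 fold change 0.63, camera adjusted p = 6.06e-06, adjusted p = 0.00528 with an estimated correlation). Among the interferon genes, 11 of 41 measured genes rose and 1 fell, 11 and 1 adjusted over the list alone (median log2 fold change 0.23, camera adjusted p = 0.00410, adjusted p = 0.0846 with an estimated correlation). Members included OAS3 at 4.08 ± 0.46. Among the GTPase and KLF genes, 10 of 27 measured genes rose and 3 fell, 11 and 5 adjusted over the list alone (median log2 fold change 0.16, camera adjusted p = 0.0387, adjusted p = 0.0847 with an estimated correlation). Members included KLF4 at 1.11 ± 0.14. That call was lost without SIMVA replicate 1 (adjusted p = 0.0507) or SIMVA replicate 2 (0.0896) and with the filter at 1 CPM (0.0602). Among the apoptosis genes, 11 of 31 measured genes rose and 4 fell, 13 and 5 adjusted over the list alone (median log2 fold change 0.13, camera adjusted p = 0.0353, adjusted p = 0.143 with an estimated correlation). Members included BIK at 3.96 ± 0.52. Leaving out SIMVA replicate 1, SIMVA replicate 2 or COMBO replicate 2 ended that call, with adjusted p from 0.0544 to 0.134. Other large changes were DYSF (dysferlin), at least 199-fold higher, RHOB, at least 300.3-fold, and JUP, at least 186-fold. Downward went LMF1 (-1.27 ± 0.22) and KATNAL2, a katanin-like gene (-1.18 ± 0.12). RRN3 and SCRIB were named as well and had replicates that disagreed (5.75 ± 4.09 and 4.38 ± 3.74 CPM, in SIMVA and in COMBO).

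The interaction asked where the change with both drugs differed from the sum of the single changes on the log2 scale. A value below 0 means a log2 change with both drugs below that sum, so a fold below the product of the single folds. The RNA can still be highest with both drugs, as it was for ITGAM and CDKN1A. Sterol synthesis genes had values below 0, such as HMGCS1 (-0.85 ± 0.08), which rose with simvastatin by 2.56 ± 0.06 alone and by 1.71 ± 0.06 on top of decitabine. ITGAM rose with each drug and had -1.70 ± 0.17, CDKN1A had -1.90 ± 0.26 and GATA2 had -2.00 ± 0.09. Upward, MUC1 stood at 0.272 ± 0.164, 0.0912 ± 0.0460 and 5.78 ± 0.582 CPM in DMSO, DAC and SIMVA and at 23 ± 1.85 CPM with both drugs (3.50 ± 0.58). Of 15000 genes, 481 had a value above 0 and 797 below at an adjusted p under 0.05, and 62 and 231 at 2-fold or more.

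Of the sterol synthesis genes, 0 lay above 0 and 18 below, 0 and 21 adjusted over the list alone (median log2 fold change -0.45, camera adjusted p = 1.72e-14, adjusted p = 6.24e-04 with an estimated correlation), with TM7SF2 at -1.68 ± 0.17. Of the fatty acid genes, 0 lay above and 6 below, 1 and 10 adjusted over the list alone (median log2 fold change -0.29, camera adjusted p = 3.40e-05, adjusted p = 0.0181 with an estimated correlation), with ACSS2 at -0.86 ± 0.10. Of the G1/S genes, 0 lay above and 13 below, 0 and 15 adjusted over the list alone (median log2 fold change -0.18, camera adjusted p = 7.48e-07, adjusted p = 0.00301 with an estimated correlation), with CDC6 at -0.56 ± 0.08. Of the germline genes, 0 lay above and 5 below, 0 and 5 adjusted over the list alone (median log2 fold change -1.94, camera adjusted p = 5.90e-16, adjusted p = 6.24e-04 with an estimated correlation), with PIWIL4 at -1.59 ± 0.11. For genes without counts in both DMSO and SIMVA, such as DAZL, this contrast reduces to COMBO against DAC, and its fitted value is no bound. Germline genes that passed the filter through counts in DAC alone favour values below 0 here.

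In the erythroid and megakaryocyte list 2 of 7 lay below 0, 2 adjusted over the list alone (median log2 fold change -1.24, camera adjusted p = 4.29e-05, adjusted p = 0.0142 with an estimated correlation), NFE2 at -1.46 ± 0.08. Only these 7 of 29 entries passed the filter, so the list's median and test can be in part set by it, as for germline genes. The progenitor and granule list had 1 above and 8 below, 2 and 8 adjusted over the list alone (median log2 fold change -0.19, camera adjusted p = 0.00237, adjusted p = 0.0694 with an estimated correlation), with MPO at -0.62 ± 0.08, RNASE2 at -1.36 ± 0.15 and MYB, a progenitor transcription factor, at -0.74 ± 0.08. Centrosome and tubulin genes had 0 above and 7 below, 0 and 8 adjusted over the list alone (median log2 fold change -0.13, camera adjusted p = 0.00692, adjusted p = 0.450 with an estimated correlation), with TUBA4A at -0.48 ± 0.07. Histone genes had 0 above and 3 below, 0 and 3 adjusted over the list alone (median log2 fold change -0.43, camera adjusted p = 0.0164, adjusted p = 0.0831 with an estimated correlation), with H2BC21 at -1.61 ± 0.23. That call was lost without COMBO replicate 1 (adjusted p = 0.0750), DMSO replicate 1 (0.0794), SIMVA replicate 2 (0.0629) or SIMVA replicate 3 (0.0702). Mitosis genes gave no call (camera adjusted p = 0.181, 0.0308 without COMBO replicate 2), with BIRC5 (survivin) as the single called member (0.33 ± 0.08). Myeloid maturation genes gave none either, with 4 above and 11 below, a median of 0.04 against a mean of -0.12 (camera adjusted p = 0.663), and CSF1R, the receptor of macrophage colony-stimulating factor, at -1.67 ± 0.14. Stress response genes had 5 above and 7 below, 8 and 8 adjusted over the list alone, and gave no call (median log2 fold change 0.10, camera adjusted p = 0.361). Those above 0 included SESN2 (1.16 ± 0.16) and CHAC1 (1.5 ± 0.32), which each drug alone had lowered.

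Across the 15000 genes, which are not independent replicates, the decitabine effect without simvastatin and with it correlated at Pearson's r = 0.796 with a slope of 0.612. Of the 7505 genes called in either, 86.0% had the same direction, and of the 3216 called in both, 3118 did and 98 did not. For simvastatin without and with decitabine, r was 0.676 and the slope 0.654, 90.03% of 10230 genes called in either had the same direction, and of 6491 called in both, 6394 did and 97 did not. The 2 contrasts of each pair share no library. Lowest with a library left out were 0.753 for decitabine (without COMBO replicate 3) and 0.598 for simvastatin (without DMSO replicate 1), and without the low-count filter r was 0.339 and 0.253. The filter was run again for each library left out, so the genes compared changed too. Every r with a library left out lay below the full value, so the drop is not credited to the library named.

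**Figure D5:**
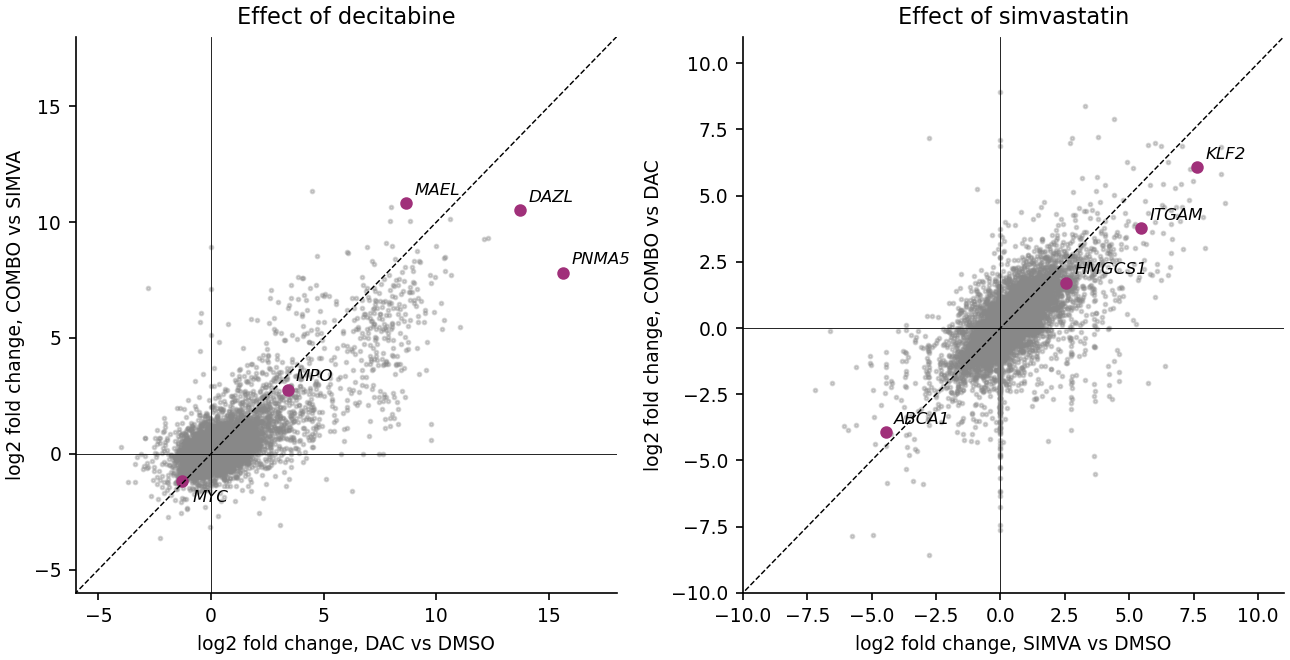
Log2 fold changes of all tested genes, decitabine alone against decitabine on top of simvastatin (left) and simvastatin alone against simvastatin on top of decitabine (right), one point per gene, with the dashed line where both would be equal. PNMA5 and DAZL, without counts in DMSO, rise in both decitabine contrasts by fitted values that rest on the prior count, and the slopes are 0.612 and 0.654.

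DAC vs DMSO and SIMVA vs DMSO shared 1375 higher and 1741 lower calls, where independent calls would give 888 and 855, and 514 and 540 genes were called in opposite directions, where independence would give 870 and 874. MYC and the ribosome biogenesis gene NCL are among shared falls, and ITGAM and CDKN1A among shared rises, while MPO and GATA2 rose with decitabine and fell with simvastatin. Both contrasts use the same DMSO libraries. On 11576 genes above 1 CPM in DMSO, the covariance of the log2 fold changes was 0.118 against 0.0169 in 20 simulations of unchanged groups, an excess of 0.101, while r was 0.304 against 0.507. With 3 control libraries the controls could not be split into separate sets with replicates for each drug, so no estimate free of the shared controls was made.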

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

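Of the tests in this part, those of library scaling, of the reordered residuals, of the pick on COMBO replicate 1, of the ribosome biogenesis list, of the G1/S list and of the sterol genes under the same selection were chosen only after the result was seen. In 1278 genes the effect of one drug differed with the other drug present, by edgeR's test of the interaction. Of 100 regroupings of the 12 libraries into 4 groups of 3, the real one included, 2 gave at least as many calls, the real value being 1278 and the highest other 7572. Regroupings across treatments put the drugs' effects into the spread between replicates, so they do not show whether chance can be excluded. With the effects of each drug taken out and the residuals dealt to the libraries anew, 1 of 100 orders, the real one, gave as many interaction calls by limma on log2 CPM. The real value was 1628 and the highest other 915. This argues against a chance order of these libraries as the source of limma's count. It does not cover the edgeR count of 1278, nor chance between cultures, since the labels do not say whether replicates were separate cultures. The regrouping with 7572 calls set all DMSO and DAC libraries on one side and all SIMVA and COMBO libraries on the other, so it holds the simvastatin effect, a structure of the samples, and the next largest gave 33 calls. For the pairwise contrasts, 1 of 10 splits of the 6 libraries, the real one, gave as many calls in each, and 10 splits are too few for a share under 0.05. Real and highest other counts were 6392 and 1 for DAC vs DMSO, 8182 and 0 for SIMVA vs DMSO, 9527 and 0 for COMBO vs DMSO, 8539 and 0 for COMBO vs DAC, and 4329 and 0 for COMBO vs SIMVA.

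Lists whose interaction passed camera were sterol synthesis (median -0.45), fatty acid synthesis (-0.29), G1/S and replication (-0.18), germline (-1.94), erythroid and megakaryocyte (-1.24), centrosome and tubulin (-0.13), progenitor and granule genes (-0.19) and histones (-0.43), and the last 3 were not called with an estimated correlation. The germline value is in part set by the filter, as said above, and the erythroid and megakaryocyte value can be too. Among called protein-coding genes with a mean of at least 5 CPM in some group, the 5 highest values were those of MUC1 (3.50), RNH1 (3.35), CEP20 (3.12), SELENBP1 (3.07) and VAMP7 (2.79). The 5 lowest among them were those of PNMA5 (-7.81), CREB5 (-7.01), GFUS (-6.12), CD93 (-5.56) and RRN3 (-4.71). PNMA5 and CD93 had no count in DMSO and CREB5 had a single one, so their values rest on the prior count of the fit. VAMP7 has a near-identical copy, so reads can be shared. RNH1, CEP20, GFUS and RRN3 had replicates that disagreed, with 109.5 ± 86.2 CPM for RNH1 in COMBO, 5.14 ± 5.81 for CEP20 in DMSO, 9.05 ± 14.5 for GFUS in DAC and 6.23 ± 4.55 for RRN3 in DAC. Without DMSO replicate 2 the call of RNH1 was lost (adjusted p = 0.0784), as was that of GFUS without DAC replicate 3 (0.252) or SIMVA replicate 1 (0.140) and that of CD93 without SIMVA replicate 3 (0.0525). CEP20 lost its call without DMSO replicate 3 (0.198), COMBO replicate 2 or 3, any DAC library, or SIMVA replicate 2 or 3, and SELENBP1 without DMSO replicate 1 (0.259), DMSO replicate 2 (0.267), COMBO replicate 2 or 3, any DAC library, or SIMVA replicate 1 or 2.

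Of the genes that the lists named in advance, FASN (-0.43), SCD (-0.29), CDKN1A (-1.90), ITGAM (-1.70), MPO (-0.62), H2BC21 (-1.61), KLF2 (-1.57) and HSPA5 (-0.20) had an interaction below 0, and ABCA1 (0.52) and ODC1 (0.25) above it. KLF2 lost its call without DAC replicate 1 (adjusted p = 0.103), DMSO replicate 1 (0.0810) or DMSO replicate 2 (0.0609). ABCA1 lost it without COMBO replicate 1 (0.0635), COMBO replicate 3 (0.0577), DAC replicate 3 (0.0534), SIMVA replicate 1 (0.0702) or SIMVA replicate 3 (0.104). HSPA5 lost it without any of COMBO replicates 2 and 3, DAC replicates 1 and 3, DMSO replicates 2 and 3 and SIMVA replicate 1 (0.0509 to 0.0898), and ODC1 without any of COMBO replicates 2 and 3, DAC replicates 1 and 3, DMSO replicates 1 and 2 and SIMVA replicates 2 and 3 (0.0520 to 0.0912).

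Genes silent in DMSO and SIMVA that decitabine raised were lower with both drugs: 158 genes picked on DAC replicate 1 had a median log2 COMBO over DAC of -1.85 in the other libraries (quartiles -2.72 and -0.94), 94.9% of them lower. A pick on DAC favours such a fall, and 50 genes picked on COMBO replicate 1 in the same way had a smaller median of -0.95 (bootstrap interval over genes -1.41 to -0.60), 74% of them lower, so the pick is not the whole cause. By library size alone the first pick had -1.77. The median of all genes in COMBO vs DAC moved only from 0.03 to 0.13 between these scalings. The choice between them could therefore not make a fall of this size, and other errors of scaling were not tested. The median log2 fall of the ribosome biogenesis list with decitabine was 0.980 times as large with simvastatin as without (bootstrap interval over genes 0.795 to 1.17), which argues against a decitabine effect that was smaller on every target alike. A candidate explanation that stays open is that fewer cells passed S phase with simvastatin, since decitabine acts when it is built into new DNA. The G1/S list was lower in COMBO than in DAC (median -0.50), as that needs. Fewer such cells would also lessen any other effect that needs the drug in DNA. The ribosome biogenesis ratio of 0.980 argues against this explanation if that list's fall is such an effect, which was not tested. RNA of mixed cells counts no cells in S phase, and uptake or conversion of the drug and faster loss of these RNAs were not tested.

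Sterol synthesis genes rose less with simvastatin when decitabine was present. With library size alone the list's median interaction was -0.45. In this contrast the scaling factors nearly cancel, as the median of all genes was -5.3e-04 with TMM and -0.0059 with library size alone. The comparison could not have come out otherwise. It shows only that the choice between these scalings did not make the pattern. Other genes that simvastatin raised at least 2-fold, 557 of them, kept 0.840 of their rise (bootstrap interval over genes 0.813 to 0.861) while the 17 sterol genes chosen by the same limits kept 0.668 (0.583 to 0.756) and all 23 called sterol genes that rose, at any size, 0.656 (0.571 to 0.729). These shares argue against an equal lessening of every simvastatin effect on the log2 scale as the whole cause, though part of the lessening may be general. A change by decitabine in the sterol demand of the cells stays open and was not tested.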

How the results depend on the processing

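A prior count of 2 in the fit and leaving out genes with disagreeing replicates or neighbours near 0 were chosen only after the result was seen. Of 13353 values of named genes under alternatives, 12795 kept direction and side of the threshold, 444 lost the call, 108 gained one and 6 reversed, and 98 that changed sign with neither value past the threshold are counted as kept. Of 2424 counts of called list members, 2294 stayed within 1.5 times. Of 2010 list test results, by camera and by fry, 1853 kept their side, 69 lost and 83 gained a call and 5 reversed. Many of the gains and all 5 reversals came from fry. With each library left out, calls ran from 5620 to 6188 in DAC vs DMSO, 7532 to 7730 in SIMVA vs DMSO, 8961 to 9205 in COMBO vs DMSO, 7808 to 7988 in COMBO vs DAC, 3443 to 4208 in COMBO vs SIMVA and 932 to 1366 in the interaction. Without the 290 genes left out for replicates that differed at least 5-fold or for neighbours near 0, calls were 6249, 8027, 9338, 8376, 4239 and 1250. Depth limits genes near the floor of 3 counts, where fitted fold changes follow the prior count. Except where said, the cause was not tested.

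Asking for a log2 fold change of at least 1 as well left 1609 genes in DAC vs DMSO (1423 higher, 186 lower), 2243 in SIMVA vs DMSO (1689, 554), 3572 in COMBO vs DMSO (2661, 911), 2525 in COMBO vs DAC (1631, 894), 901 in COMBO vs SIMVA (852, 49) and 293 in the interaction (62, 231), fewer by construction. On TPM without the filter, 1709 genes were lower in DAC vs DMSO and 317 above 0 in the interaction. Lower calls in COMBO vs SIMVA were 1400 with library size alone, 1243 on log2(TPM + 1), 1210 on log2(TPM + 0.1) and 1007 on TPM without the filter. Of the list tests, 38 passed with an estimated correlation and 124 with fry, which does not compare a list with other genes.

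ELANE reversed in DAC vs DMSO without DAC replicate 1 (-0.52, adjusted p = 0.0215), with values up to 0.29 without another library. In COMBO vs DMSO, CHEK1 reversed with library size alone (0.00367), and MCL1 with library size alone (0.0427), on log2(TPM + 1) (0.0216), on log2(TPM + 0.1) (0.0216) and on TPM without the filter (0.0216), none of these past the threshold. Fry turned the direction of sterol efflux in SIMVA vs DMSO (adjusted p = 0.0310) and COMBO vs DAC (2.82e-05), fatty acid synthesis in COMBO vs DMSO (2.09e-06) and COMBO vs DAC (9.37e-05), and progenitor and granule genes in COMBO vs SIMVA (0.00896).

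Correlations and slopes count as moved when they changed by more than a jackknife SE over the 12 left-out libraries. With a library left out the filter was run again, so such a move can come from the changed set of genes. The decitabine r of 0.796 became 0.339 without the filter, 0.831 with the filter at 1 CPM, 0.643 on log2(TPM + 1), 0.708 on log2(TPM + 0.1), 0.434 on TPM without the filter and 0.734 with the prior count of 2, and 0.753 to 0.766 with a library left out. Its slope of 0.612 became 0.294, 0.471 on log2(TPM + 1), 0.520 on log2(TPM + 0.1), 0.359 on TPM without the filter and 0.535 with the prior count of 2. The simvastatin r of 0.676 became 0.253 without the filter, 0.743 with the filter at 1 CPM, 0.793 on log2(TPM + 1), 0.730 on log2(TPM + 0.1) and 0.733 with the prior count of 2, and 0.598 to 0.638 with a library left out, 0.598 to 0.629 among those that moved. Its slope of 0.654 became 0.275, 0.852 on log2(TPM + 1), 0.773 on log2(TPM + 0.1) and 0.780 with the prior count of 2.

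With replicate number as a block, 809 genes lay above 0 in the interaction in place of 481, camera calls were lost for NF-kB genes in COMBO vs DAC (adjusted p = 0.0675), histones in COMBO vs DMSO (0.0594) and small GTPase and KLF genes in SIMVA vs DMSO (0.0795) and COMBO vs SIMVA (0.0592), and gained for centrosome and tubulin genes in DAC vs DMSO (0.0351) and DNA repair in the interaction (0.0409). The labels do not say that the numbers pair samples, and 10 of 18 pairs of libraries with the same number had a residual correlation over 0.1 (range -0.149 to 0.361), so the block is given as an alternative alone.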

Other observations

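The genes and regions in this part, and the test of genes that all cells use, were chosen only after the result was seen. HGF, the hepatocyte growth factor, stood at 9.80 ± 0.476 CPM in DMSO, 187 ± 15.5 in DAC, 11.7 ± 0.844 in SIMVA and 23.1 ± 2.86 in COMBO (SD, n = 3), an interaction of -3.28. ANXA1, which encodes annexin A1 of myeloid cells, stood at 59.9 ± 1.37, 354 ± 13.9, 143 ± 7.34 and 143 ± 8.46 CPM in the same order, an interaction of -2.56. S100A4, a calcium-binding protein gene, stood at 41.0 ± 3.89 and 54.9 ± 2.75 CPM without simvastatin and at 1186 ± 44.5 and 1123 ± 43.2 CPM with it (log2 fold change 4.85 ± 0.07 in SIMVA vs DMSO).

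TP63, which encodes a transcription factor of squamous epithelia, stood at 1.04 ± 0.355 CPM in DMSO, 10.8 ± 1.32 in DAC, 21.2 ± 2.82 in SIMVA and 18.1 ± 1.45 in COMBO. Its log2 fold changes against DMSO were 3.38 ± 0.20, 4.36 ± 0.19 and 4.13 ± 0.19 (adjusted p = 3.59e-11, 1.00e-13 and 1.14e-13).

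In the MHC block on chromosome 6, from 29 to 33 Mb, 130 of 153 protein-coding genes (85.0%) were listed near 0, at 36 counts or fewer over the 12 libraries, against 334 of 887 (37.7%) elsewhere on that chromosome. Of 17 genes there that all cells use, 14 were under 1 CPM, which argues against silence in these cells. Replicates differed at least 5-fold in 51 of 10553 expressed protein-coding genes. Of their 10 nearest genes 40.8% were near 0 against 31.9% for random genes of matched expression (permutation p = 6e-04, one-sided, 10000 draws). Many of the 51 share neighbours, so this p may be too small. Read loss where the reference repeats a sequence, such as alternate MHC copies, stays open for the genes near 0, since no alignments were analysed. Why replicates differ was not tested. Disagreeing genes made 18 of the 2-fold calls in DAC vs DMSO, 11 among the 186 lower.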
